A study of Mus musculus with 3 samples.

How the data were processed

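Single GFP-positive cones were sorted by FACS from papain-dissociated mouse retina of 3 lines (wildtype Chrnb4-GFP, Cnga3-/- and Pde6ccpfl1), with a viability dye, into one 96-well plate per line, and libraries were made by the authors with a protocol adapted from SMARTseq2 and MARS-seq. There is 1 library per genotype. All are labelled postnatal day 12. The well names also carry a tag that differs between the plates, whose meaning is not stated. If the tag is an age, age is confounded with genotype. The deposited table holds raw counts per gene and well, with 31053 genes and 208 wells, of which 8684 genes have no count in any well. Per the labels, featureCounts (no version) and the genome build GRCh38 were used. That build is human and the gene names are mouse symbols, of which 30464 (98.1%) are in the GENCODE M21 annotation of GRCm38, so the build given was not used here. The aligner, the handling of molecular identifiers and any filter on cells by the authors are not given in the labels, so counts may not be independent molecules, and intervals and floors cover counting error only.

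Every well was matched to its library by the name in its column. Cells were kept with at least 500 genes with a count and at most 30% of counts on mitochondrially encoded genes, which left 183 cells. The 25 wells left out were 9 wildtype, 6 Cnga3-/- and 10 Pde6ccpfl1 wells. No doublet caller was run, since each well was sorted to hold a single cell, and no well was removed as a doublet. Kept cells held 273080 to 335499 counts per library and 1061 to 16935 counts per cell.

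Counts of kept cells were summed per library and scaled to the library total as CPM. Genes were compared when they had at least 50 counts over the 2 libraries and a count in at least 20% of the kept cells of one. The log2 ratio of CPM has an exact 95% interval conditional on the total count, and CPM has an exact Poisson interval. A library with 0 counts of a gene was set to a floor of 3 counts, and the ratio is then a bound. With 1 library per genotype no p-value, standard error or number of changed genes was computed. Numbers of genes at least 2-fold apart describe size.

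The rules that follow were fixed before the data were examined. Named genes were, in each comparison, the 12 with the highest and the 12 with the lowest log2 ratio among compared genes at least 2-fold apart whose direction was the same in the mean CPM over cells and in the share of cells with a count, and which were at least 1.5-fold apart the same way in each pairing of odd-numbered and even-numbered cells. Predicted genes, pseudogenes and mitochondrially encoded genes were left out of this ranking. Results of some genes that are withheld for evaluation are left out of the text. Also named were the targeted genes, Chrnb4, sex-linked genes, the members of 21 gene lists with the largest ratios and the cone phototransduction genes. The lists were cone phototransduction, rod genes, other retinal cell types, photoreceptor transcription factors, nuclear migration and microtubule motors, actin and myosin, adhesion and guidance, ribbon synapse, outer segment and cilium, ER stress and protein folding, cell death, cGMP with calcium and calpain, nuclear oxidative phosphorylation, mitochondrially encoded, glycolysis and lactate, oxidative stress response, immediate early and heat shock, photoreceptor injury with immune and growth factors, proteasome and ubiquitin, cytosolic ribosomal proteins, and sex-linked. Some genes are in more than one list. For each list the summed counts were compared, and with at least 3 compared members the median log2 ratio was placed among 10000 random lists of the same size matched in 10 bins of expression. A median outside the middle 95% stands apart.

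For 13 sets of cell type markers, the share of cells with a count was taken after thinning each cell to 1400 counts, with shallower cells left out (48 wildtype, 65 Cnga3-/- and 54 Pde6ccpfl1 cells remained), with exact Clopper-Pearson intervals. Clusters were Leiden clusters from scanpy 1.11.5 on 2000 variable genes, 15 principal components, 15 neighbours and resolution 0.5. The correlation of the mutant comparisons was set beside 100 simulations of unchanged groups drawn from wildtype cells and beside a split of the wildtype cells. CPM per kilobase used the union of annotated exons in GENCODE M21, and this measure was added after the data were seen, as was the use of olfactory receptor genes as a reference.

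The alternatives were no cell filter and a stricter one (1000 genes, 15% mitochondrial counts), the mean CPM over cells, median-of-ratios factors, TMM factors from edgeR 4.0.16, CPM without mitochondrially encoded genes and the 20 most abundant genes, only cells with at least 3 cone markers detected, thinned cells, odd-numbered or even-numbered cells, leaving out the 5 deepest cells of each library, gene filters of 10 counts and of 200 counts, unthinned shares and cluster resolution 1. Scaling to the sum of nuclear oxidative phosphorylation and ribosomal protein genes, use of only the wells kept in all 3 plates, and list sums without the 2 members with the most counts over the 3 libraries, were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and matplotlib 3.10.9 were used.

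The comparison was tested on simulated data with 200 genes changed by a known fold and counting noise alone. Of the unchanged genes compared, 2 of 1530, 2 of 1437 and 1 of 1586 came out at least 2-fold higher, and 4, 3 and 9 at least 2-fold lower. Genes set 4-fold apart came out at least 2-fold apart in 100%, 98.8% and 100% of cases, and genes set 2-fold apart had the right direction in 100% of cases in each comparison. Simulated libraries hold no variation between plates, so these rates do not describe the error of a comparison between genotypes.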

Results

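The data were counts per gene from single GFP-positive cones sorted from mouse retina, with 1 plate, and so 1 library, for each of 3 lines. The wildtype line carried the Chrnb4-GFP reporter, which marks cones. The Cnga3-/- line lacks a subunit of the cyclic nucleotide-gated channel that carries the cone light response. The Pde6ccpfl1 line carries a mutation in the catalytic subunit of the cone phosphodiesterase. All 3 libraries were labelled postnatal day 12, and the series is about the migration of cones in normal and degenerating retina. The wildtype plate held 61 wells with counts, the Cnga3-/- plate 76 and the Pde6ccpfl1 plate 71, of which 52, 70 and 61 cells were kept. Kept cells held 273080 counts in wildtype, 335499 in Cnga3-/- and 295011 in Pde6ccpfl1. The median per kept cell was 4895 counts (range 1061 to 11671) in wildtype, 4056.5 (1134 to 16935) in Cnga3-/- and 3796 (1106 to 16039) in Pde6ccpfl1. The median number of genes per cell was 1829, 1473.5 and 1376 in the same order. With 1 library per genotype no test between genotypes was possible, cells are not replicates, and genotype cannot be told apart from plate. Intervals are 95% and cover counting error only.

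**Figure D1:**
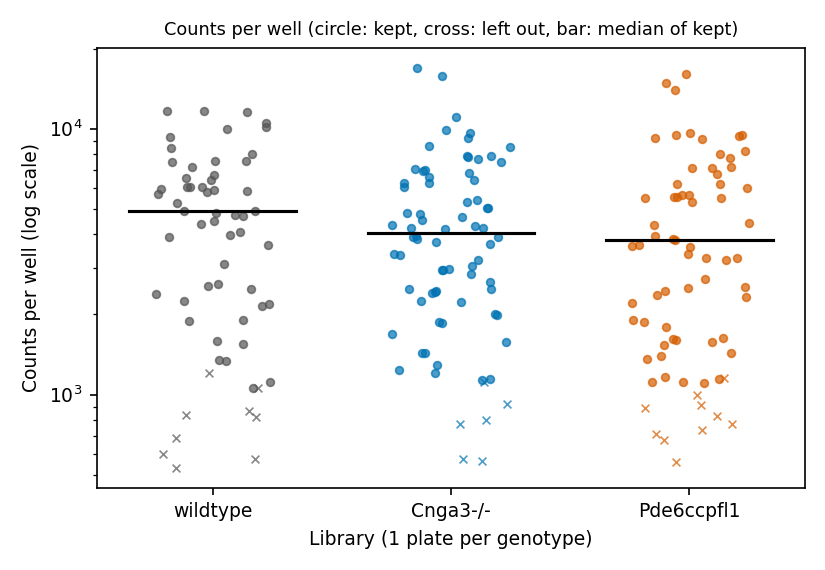
Counts per well (vertical axis, log scale) in the wildtype, Cnga3-/- and Pde6ccpfl1 libraries, with a circle for each kept cell, a cross for each well left out and a bar at the median of the kept cells. The medians lie at 4895, 4056.5 and 3796 counts, and the deepest cell, with 16935 counts, is in the Cnga3-/- library.

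The most abundant genes in these cells were not photoreceptor genes. Over the 3 libraries the leading gene was Pcdhb13, a protocadherin, at 26717 CPM (counts scaled to the library total) in wildtype, 19529 in Cnga3-/- and 28402 in Pde6ccpfl1. Cttnbp2nl, Trpm4, Slc34a2 and Shroom2 also stood at over 10000 CPM in each library, with a count in 100% of kept cells. The 10 genes most abundant over the 3 libraries together took 13.2% of counts in wildtype, 19.7% in Cnga3-/- and 17.9% in Pde6ccpfl1. They include Kif23, Smtnl1 and Il18, with 0.00989%, 0.00293% and 0.124% of wildtype counts, so this joint ranking lowers the wildtype share. Mitochondrially encoded genes took 0.0681%, 0.0641% and 0.0658% of counts, and ribosomal protein genes 0.105%, 0.186% and 0.205%. Olfactory receptor genes, which serve smell in the nasal epithelium, took 1.65%, 1.32% and 1.52%. Opn1sw, the short-wavelength cone opsin, ranked 1233 among 21750 protein-coding genes by its 90 counts over the 3 libraries, and Arr3, cone arrestin, ranked 3263 with 35 counts.

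The targeted genes had few counts. Cnga3 (chromosome 1, 37214434 to 37263384 in the GRCm38 annotation) had 22 counts in wildtype, 13 in Cnga3-/- and 3 in Pde6ccpfl1. The log2 ratio of Cnga3-/- over wildtype was -1.06 (-2.17 to -0.00), and the log2 ratio of Pde6ccpfl1 over wildtype was -2.99 (-5.37 to -1.25). Pde6c (chromosome 19, 38132781 to 38183958) had 0 counts in wildtype, 5 in Cnga3-/- and 2 in Pde6ccpfl1. The table counts whole genes, so counts outside the deleted or mutated part check nothing about the genotype. Chrnb4, the driver of the reporter (chromosome 9, 55028154 to 55048779), had 71, 75 and 36 counts, with a log2 ratio of -0.22 (-0.71 to 0.27) in Cnga3-/- and -1.09 (-1.71 to -0.49) in Pde6ccpfl1 over wildtype. GFP had no entry in the table. Xist, the RNA that silences an X chromosome in females, had 36, 19 and 15 counts, and the Y-linked gene Kdm5d had 7, 13 and 12.

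Summed cone markers and summed rod markers were lower in the wildtype library than in either mutant library. With each cell thinned to 1400 counts, 4 of 48 wildtype cells (8.33%, exact binomial interval 2.32 to 20.0) had a count of any of 12 cone markers, against 41 of 65 Cnga3-/- cells (63.1%, 50.2 to 74.7) and 40 of 54 Pde6ccpfl1 cells (74.1%, 60.3 to 85.0). Without thinning the counts were 21 of 52, 60 of 70 and 56 of 61 cells. The 12 cone markers summed to 53 counts in wildtype, 259 in Cnga3-/- and 218 in Pde6ccpfl1, a ratio to wildtype of 3.98 (2.95 to 5.45) and 3.81 (2.81 to 5.24). Opn1sw had 0, 63 and 27 counts, which makes it at least 17.1-fold higher in Cnga3-/- and at least 8.33-fold higher in Pde6ccpfl1, against a floor of 3 counts in the wildtype library. Gnat2, the cone transducin, had 0, 20 and 20 counts, and Gngt2, its gamma subunit, 0, 22 and 43. Opn1mw, the medium-wavelength opsin, had 4, 17 and 21 counts. Any of 12 rod markers was counted in 29.2% of thinned wildtype cells, 56.9% of Cnga3-/- cells and 59.3% of Pde6ccpfl1 cells, with sums 1.95 (1.56 to 2.46) and 1.65 (1.30 to 2.10) times that of wildtype. Some markers went the other way and were highest in wildtype: Cnga3, the rod phosphodiesterase subunit Pde6a with 42, 34 and 21 counts, and the rod transcription factor Nrl with 11, 6 and 9. The wider list of 29 cone phototransduction genes had 3058 CPM in wildtype, 2873 in Cnga3-/- and 3851 in Pde6ccpfl1.

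Among the other cell types, thinned cells with a count of a horizontal cell marker made up 33.3% in wildtype, 24.6% in Cnga3-/- and 25.9% in Pde6ccpfl1. The shares were 27.1%, 15.4% and 14.8% for Muller glia and 31.2%, 24.6% and 16.7% for bipolar cells. Amacrine markers gave 14.6%, 9.23% and 13.0%, and retinal ganglion markers 12.5%, 6.15% and 20.4%. Endothelium and pericyte markers gave 22.9%, 18.5% and 25.9%, astrocyte markers 10.4%, 10.8% and 16.7%, and cell cycle genes 10.4%, 9.23% and 16.7%. Microglia markers gave 4.17%, 4.62% and 5.56%, and pigment epithelium markers 6.25%, 6.15% and 7.41%. Erythrocyte markers had 0, 2 and 0 counts, none of them in the thinned cells, with upper limits of 7.40%, 5.52% and 6.60% of cells. These are shares of cells with a count and not shares of cells of each type. Per kilobase of exon, most of these marker sets lay near or below the olfactory receptor genes. Horizontal cell markers lay above them in each library.

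Per kilobase of exon, the cone markers of the wildtype library lay at the level of olfactory receptor genes, a comparison chosen after the data were seen. In wildtype the cone markers had 4.91 CPM per kilobase (3.67 to 6.42) and the 1133 olfactory receptor genes 4.51. The cone markers had 19.5 (17.2 to 22.0) in Cnga3-/- and 18.7 (16.3 to 21.3) in Pde6ccpfl1, with olfactory receptors at 3.61 and 4.17. The wider list of 29 cone phototransduction genes stood higher in wildtype, at 19.7, against 18.6 in Cnga3-/- and 24.9 in Pde6ccpfl1. Abca4 held 493 of the 835 wildtype counts of that list. Rod markers stood at 7.68, 15.0 and 12.7 CPM per kilobase, nuclear oxidative phosphorylation genes at 6.20, 11.4 and 11.8, and ribosomal protein genes at 6.27, 11.1 and 12.3. Mitochondrially encoded genes stood at 59.7, 56.2 and 57.7, and markers of the other retinal cell types at 4.60, 3.76 and 4.07. Among these other types, horizontal cell markers were the highest in each library, at 10.1, 7.46 and 8.65. Muller glia markers stood at 5.37, 3.23 and 2.19, bipolar markers at 2.84, 3.21 and 2.88, and amacrine markers at 2.76, 2.51 and 2.48.

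**Figure D2:**
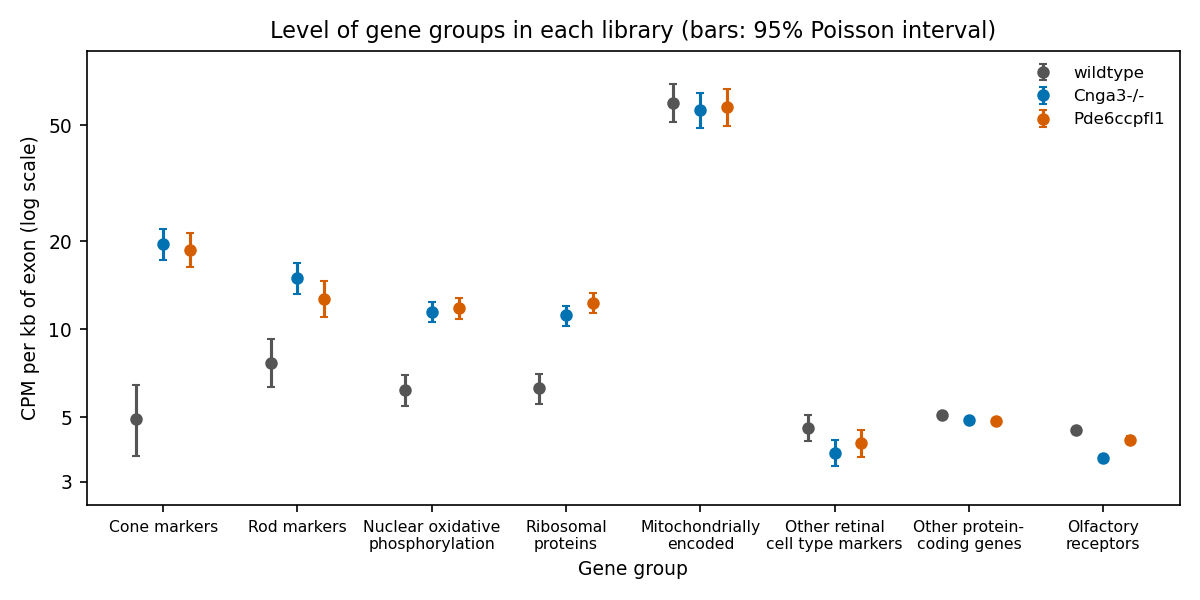
Level of each gene group (vertical axis, CPM per kilobase of exon, log scale) in the wildtype, Cnga3-/- and Pde6ccpfl1 libraries, with a point per library and a bar for the 95% Poisson interval, which covers counting error only. Cone markers lie at 4.91 in wildtype against 19.5 and 18.7 in the mutants, while mitochondrially encoded genes lie between 56.2 and 59.7 in all 3 libraries.

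The Cnga3-/- library was compared with the wildtype library. Genotype cannot be told apart from plate here, and cone markers in wildtype lay at the level of olfactory receptor genes. The largest ratios among the consistently ordered genes belonged to Smtnl1, a smoothelin-like muscle protein, and Kif23, a kinesin of cell division. Smtnl1 (chromosome 2, 84811176 to 84822652) had 2952 counts in Cnga3-/- and 8 in wildtype, a log2 ratio of 8.23 (7.25 to 9.44). Kif23 (chromosome 9, 61915905 to 61946774) had 6608 against 27 counts, a log2 ratio of 7.64 (7.10 to 8.24), and a count in 100% of Cnga3-/- cells against 36.5% of wildtype cells. Ercc4, a DNA repair endonuclease, was 76.1-fold higher (841 against 9 counts) and Themis3 55.7-fold higher (821 against 12). The other 8 of the 12 highest were Taok1, Olfr410, Gje1, Slc38a11, Zfp526, Isy1, Tlk2 and Twsg1. They had 1 to 3 counts in wildtype and log2 ratios from 5.46 (3.89 to 7.75) for Twsg1 to 6.67 (4.16 to 11.98) for Taok1. Among the 12 lowest were Pdzd9, Olfr95, Rarres2, Myh7, Nat3, Vmn1r74, Taf1, Hadhb, Adarb2, Wnt16 and Rnf32. They ran from 16.0-fold lower for Pdzd9 (4 against 52 counts) to 5.71-fold lower for Rnf32 (59 against 274). The heart muscle myosin Myh7 was 10.0-fold lower (14 against 114 counts).

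By gene list, rod genes, photoreceptor transcription factors, nuclear oxidative phosphorylation genes and ribosomal proteins were among those with higher sums in Cnga3-/- than in wildtype. The rod genes summed to 440 against 139 counts, a ratio of 2.58 (2.12 to 3.14), and their median log2 ratio of 2.36 over 5 tested members lay at the 99.6th percentile of random lists, which stands apart. Pde6g had 50 counts against 1, a log2 ratio of 5.35 (2.80 to 10.68), Gnb1 46 against 5 and Samd7 63 against 10, while Pde6a and Sag lay within 2-fold. The median of the 5 is the value of Samd7, which is also in the list of photoreceptor transcription factors. Pde6g, Gnb1 and Samd7 reached the filter of 50 counts only through their counts in Cnga3-/-. With the stricter cell filter 3 rod genes were tested and their median was 0.19. Over all lists and comparisons, only the rod gene median here and the ribosomal protein median between the mutants stood apart. With many lists placed, some stand apart by chance. Photoreceptor transcription factors summed to 2.70 times the wildtype level (2.32 to 3.15), mostly through the nuclear receptor Rora with 440 against 60 counts, and without Rora and Samd7 the ratio was 1.26 (1.02 to 1.55). The ratio was 1.85 (1.59 to 2.14) for nuclear oxidative phosphorylation genes, 1.78 (1.54 to 2.05) for cytosolic ribosomal proteins, 1.14 (1.02 to 1.27) for outer segment and cilium genes and 1.11 (1.01 to 1.23) for ribbon synapse genes. The last 3 turn below 1 when libraries are scaled to the nuclear oxidative phosphorylation and ribosomal sums, a scaling that by its construction brings the oxidative phosphorylation and ribosomal lists near 1, and the ribbon synapse list also turned with thinning and in cells with at least 3 cone markers.

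Lower sums in Cnga3-/- than in wildtype were found for cell death at 0.599 (0.554 to 0.649), actin and myosin at 0.657 (0.614 to 0.702), ER stress and protein folding at 0.772 (0.679 to 0.877), proteasome and ubiquitin at 0.778 (0.698 to 0.868) and adhesion and guidance at 0.836 (0.775 to 0.901). Cell death and proteasome and ubiquitin turned above 1 in cells with at least 3 cone markers, and the actin list in even-numbered cells. Most of the cell death counts were from Parp1, a DNA damage sensor, with 441 against 673 counts, and the executioner caspase Casp6, with 399 against 563, of 1092 against 1483 in all. Without the 2 members with the most counts in each list, a check added after the data were seen, the ratio was 0.830 (0.694 to 0.994) for cell death and 0.879 (0.811 to 0.953) for adhesion and guidance. It turned to 1.38 (1.22 to 1.56) for actin and myosin, 1.31 (1.06 to 1.63) for ER stress and protein folding and 1.19 (0.959 to 1.47) for proteasome and ubiquitin, whose largest members were Myo6, Creld2 and Ube2n. In the actin list the motor Myo6 had 647 against 1357 counts, while Arhgef7 had 119 against 8 and the actin-binding peptide Tmsb10 had 66 against 6. Of 10 tested genes of nuclear migration and microtubule motors, the dynein heavy chain Dync1h1 was 2.83-fold higher (73 against 21 counts) and the other 9 lay within 2-fold, with a list ratio of 0.989 (0.904 to 1.08). The interval also included 1 for cone phototransduction (0.940), other retinal cell types (0.864), cGMP, calcium and calpain (0.925), mitochondrially encoded genes (0.941), glycolysis and lactate (1.07), oxidative stress response (1.04), immediate early and heat shock (0.945), photoreceptor injury (0.986) and sex-linked genes (0.773). Without the 2 members with the most counts the interval left 1 for photoreceptor injury at 0.746 (0.612 to 0.909), glycolysis and lactate at 1.23 (1.007 to 1.495), nuclear migration and microtubule motors at 1.11 (1.002 to 1.234) and cone phototransduction. Abca4, a retinoid transporter also found in rods, made up 359 of the 964 cone phototransduction counts in Cnga3-/- and 493 of the 835 in wildtype, and without Abca4 and Rdh12 the ratio was 1.85 (1.59 to 2.16).

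Of 1723 genes compared between Cnga3-/- and wildtype, 193 were at least 2-fold higher and 202 at least 2-fold lower, as a description of size and not as tested changes. The median log2 ratio of these genes was -0.32, and -0.18 with median-of-ratios scaling, where the numbers were 219 higher and 140 lower. Scaled to the nuclear oxidative phosphorylation and ribosomal sums, the median was -1.18 and the numbers were 131 higher and 1008 lower. Both numbers moved by over 1.5 times with thinning, with either other gene filter and in the wells kept in all 3 plates, where 78 were higher and 88 lower. The number higher was 120 in odd-numbered and 118 in even-numbered cells. Gje1, Tlk2 and Twsg1 were lower in Cnga3-/- when cells with at least 3 cone markers alone were used, which left 2 wildtype cells.

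The Pde6ccpfl1 library was compared with the same wildtype library, so that genotype again cannot be told apart from plate. Smtnl1 and Kif23 again led, with 8095 against 8 counts and a log2 ratio of 9.87 (8.89 to 11.08) for Smtnl1 and 9007 against 27 counts and 8.27 (7.73 to 8.87) for Kif23. The olfactory receptor Olfr845 had 488 counts and none in wildtype, at least 151-fold higher. Themis3 was 142-fold higher (1839 against 12 counts). The other 8 of the 12 highest were Taok1, Zfp526, Pvrig, Twsg1, Olfr410, Gje1, Slc38a11 and Npepps, with 1 to 3 counts in wildtype and log2 ratios from 5.82 (3.29 to 11.15) for Npepps to 6.78 (4.28 to 12.10) for Taok1. Lowest were the acetyltransferase Nat3 at 2 against 113 counts, a log2 ratio of -5.93 (-8.99 to -4.05), and Lhfp, 33.7-fold lower with 5 against 156 counts. The next 10 included Wnt16, Pdzd9, Vmn1r74, Taf1, Rnf32, Pgrmc2, Vmn2r108, Zfp143 and Gnpda2, from 28.4-fold lower for Wnt16 (4 against 105 counts) to 13.4-fold lower for Gnpda2 (5 against 62).

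The list sums that were higher in Pde6ccpfl1 than in wildtype again included photoreceptor transcription factors at 3.35 (2.88 to 3.90), with Rora at 566 against 60 counts (1.25, 1.01 to 1.55, without Rora and Samd7), rod genes at 1.96 (1.59 to 2.41), cytosolic ribosomal proteins at 1.96 (1.70 to 2.27) and nuclear oxidative phosphorylation at 1.90 (1.64 to 2.21), the last at 3.02 (2.496 to 3.66) without its 2 members with the most counts. Fewer than 3 rod genes were tested, so their median was not compared with random lists. Smaller ratios were found for glycolysis and lactate at 1.30 (1.10 to 1.54), cone phototransduction at 1.26 (1.15 to 1.38) and photoreceptor injury, immune and growth factor at 1.25 (1.11 to 1.40). These 3 and the oxidative phosphorylation list turned below 1 with the scaling to oxidative phosphorylation and ribosomal sums, and the log2 ratio of the rod genes went from 0.97 to 0.02. In the injury list the oncostatin M receptor Osmr had 46 against 16 counts and Stat3 514 against 292. This list also turned below 1 in odd-numbered cells, and to 0.723 (0.588 to 0.889) without Stat3 and Igf1r. The cone phototransduction ratio without Abca4 and Rdh12 was 1.80 (1.53 to 2.11).

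Lower sums in Pde6ccpfl1 than in wildtype were found for cell death at 0.593 (0.546 to 0.644), with Parp1 at 489 against 673 and Casp6 at 220 against 563 counts, for actin and myosin at 0.806 (0.755 to 0.861), for adhesion and guidance at 0.876 (0.812 to 0.946) and for nuclear migration and microtubule motors at 0.886 (0.806 to 0.974). The actin list turned above 1 in even-numbered cells and in cells with at least 3 cone markers. Without the 2 members with the most counts the ratio was 0.903 (0.753 to 1.08) for cell death, where these were Parp1 and Casp6, 0.987 (0.884 to 1.10) for nuclear migration and microtubule motors and 0.825 (0.758 to 0.899) for adhesion and guidance. Within the actin list Tmsb10 was 22.8-fold higher (148 against 6 counts). Among 7 tested migration and motor genes, the kinesin Kif5a had 49 against 5 counts and Dync1h1 83 against 21, and the other 5 lay within 2-fold. The adhesion gene Cntn4 was 3.63-fold higher and Nectin3 3.62-fold lower. Intervals included 1 for other retinal cell types (0.829), ribbon synapse (1.02), outer segment and cilium (1.07), ER stress and protein folding (1.05), cGMP, calcium and calpain (0.995), mitochondrially encoded genes (0.965), oxidative stress response (1.22), immediate early and heat shock (1.02), proteasome and ubiquitin (1.00) and sex-linked genes (0.764). Of these, without the 2 members with the most counts, the interval left 1 for outer segment and cilium at 1.30 (1.134 to 1.501), ER stress and protein folding at 1.30 (1.04 to 1.62) and oxidative stress response at 1.38 (1.004 to 1.912). No list median stood apart from random lists in this comparison.

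Of 1600 genes compared between Pde6ccpfl1 and wildtype, 163 were at least 2-fold higher and 244 at least 2-fold lower. Their median log2 ratio was -0.16, -0.07 with median-of-ratios scaling and -0.06 with TMM scaling. Scaled to the oxidative phosphorylation and ribosomal sums, the median was -1.11, with 118 genes higher and 914 lower. In the wells kept in all 3 plates 80 genes were higher and 160 lower, and thinning and the other gene filters also moved both numbers by over 1.5 times. Slc38a11 was lower in Pde6ccpfl1 when cells with at least 3 cone markers alone were used.

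The comparison of Pde6ccpfl1 with Cnga3-/- sets the mutant lines side by side. Olfr845 was 10.3-fold higher in Pde6ccpfl1 (488 against 54 counts) and the RNA-editing family gene Adarb2 9.54-fold higher (109 against 13). Next were Sbf1, Cfap61, Nfyb, B3gnt9, Tmem245, Syt5, Rlf, Slc6a2, Rnf122 and Osmr, from 5.62-fold for Sbf1 to 2.62-fold for Osmr. Lowest in Pde6ccpfl1 were the deubiquitinase family gene Usp13, 8.43-fold lower (12 against 115 counts), and the actin-bundling protein Fscn1, 8.17-fold lower (7 against 65). The next 10 were Rapsn, Mcpt8, Arhgap25, Tmem30c, Trdn, Wdr27, Tmem110, Extl3, Sult2b1 and Dnaaf3, from 7.18-fold lower for Rapsn to 5.42-fold lower for Dnaaf3. The cone marker sums had a ratio of 0.957 (0.796 to 1.15). Within cone genes Opn1sw had 27 counts in Pde6ccpfl1 against 63, Arr3 27 against 5 and Gngt2 43 against 22.

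Between the mutants, list sums were higher in Pde6ccpfl1 for ER stress and protein folding at 1.37 (1.21 to 1.55), cone phototransduction at 1.34 (1.23 to 1.46), proteasome and ubiquitin at 1.29 (1.16 to 1.44), photoreceptor injury at 1.26 (1.14 to 1.41), photoreceptor transcription factors at 1.24 (1.12 to 1.37), actin and myosin at 1.23 (1.15 to 1.32) and glycolysis and lactate at 1.22 (1.04 to 1.42). They were lower for rod genes at 0.760 (0.653 to 0.883) and for nuclear migration and microtubule motors at 0.896 (0.819 to 0.981), in which Clasp1, Map1b and Dctn4 had 18, 18 and 16 counts against 69, 63 and 37. The transcription factors turned below 1 in odd-numbered cells and in cells with at least 3 cone markers, and the migration and motor genes above 1 with thinning. Without the 2 members with the most counts, 5 of these lists turned below 1: ER stress and protein folding (0.992), cone phototransduction (0.971), proteasome and ubiquitin (0.921), photoreceptor injury (0.970) and photoreceptor transcription factors (0.997). The median of 5 tested ribosomal protein genes was 0.81, at the 98.7th percentile of random lists, which stands apart, although Rps19 was lower at 16 against 48 counts and the list sum was 1.10 (0.984 to 1.24). With a filter of 10 counts 45 cytosolic ribosomal proteins were compared and the median was 0.19. Intervals included 1 for other retinal cell types (0.960), adhesion and guidance (1.05), ribbon synapse (0.915), outer segment and cilium (0.941), cell death (0.989), cGMP, calcium and calpain (1.08), nuclear oxidative phosphorylation (1.03), mitochondrially encoded genes (1.03), oxidative stress response (1.18), immediate early and heat shock (1.08) and sex-linked genes (0.988). Without the 2 members with the most counts, ribbon synapse was at 0.715 (0.635 to 0.804) and nuclear oxidative phosphorylation at 1.29 (1.12 to 1.47), and the other intervals in this group still included 1. Of 1693 genes, 109 were at least 2-fold higher and 158 at least 2-fold lower, and 82 and 197 with the scaling to oxidative phosphorylation and ribosomal sums. Thinning and the other gene filters moved both numbers by over 1.5 times, and 229 genes were higher in odd-numbered cells.

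Many of the genes that stood apart from wildtype did so in both mutant libraries. Across 1480 genes compared in both, which are not independent replicates, the log2 ratios had Pearson r = 0.855 and Spearman correlation = 0.532. Both comparisons share the wildtype library. With wildtype cells split between them r was 0.541 and the covariance 1.08, where the counts are no longer shared but the plate still is. Each part of the split also holds fewer wildtype counts. Simulations of unchanged groups that share a library gave a mean r of 0.553 with a maximum of 0.795 over 100 runs, and a covariance of 0.290 against the measured 1.56. Since they share a library, they are not a reference for the r of the split. Genes at least 2-fold higher in both numbered 114, against a mean of 49.7 and a maximum of 157 in these simulations. Those lower in both numbered 102, against a mean of 34.5 and a maximum of 87. All simulated groups were drawn from the wildtype plate, so they hold no variation between plates. Values of r, covariance or gene numbers beyond the simulated ones can therefore come from plate as well as from genotype. The simulated range for genes higher in both cannot judge the 114. Some compared genes, such as Taok1 with 1 wildtype count, leave almost nothing to draw from wildtype cells. Their simulated ratios can then rest on the floor set for a library without counts. These ratios also enter the simulated r and covariance.

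**Figure D3:**
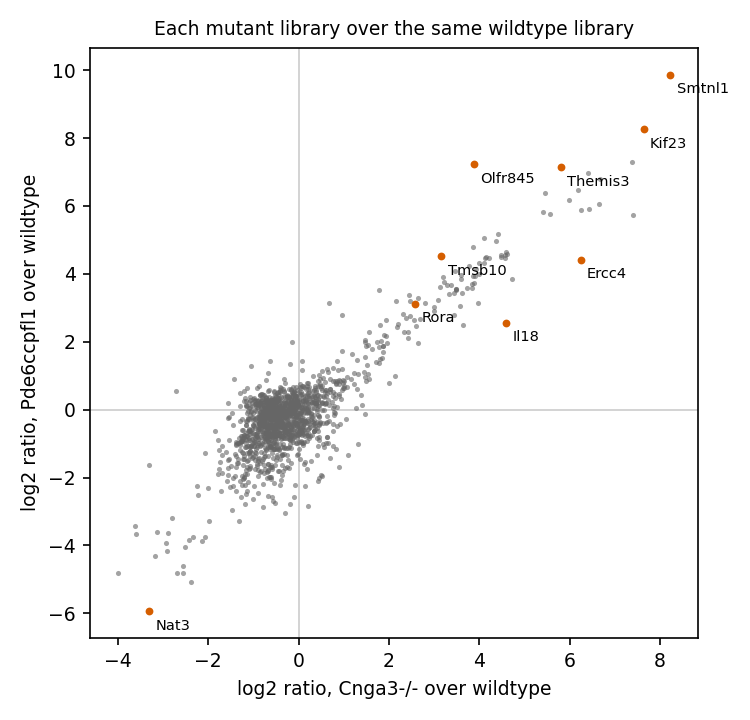
Log2 ratio over wildtype of each of 1480 genes in Cnga3-/- (horizontal axis) and in Pde6ccpfl1 (vertical axis), with a point per gene and the genes named in orange. The outlying points lie along the diagonal (Pearson r = 0.855, with the wildtype library shared), and Smtnl1 lies farthest out at 8.23 and 9.87.

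Clustering of the kept cells largely separated the plates. At resolution 0.5 there were 3 clusters of 50, 71 and 62 cells. The first held 47 of the 52 wildtype cells, the next 58 of the 70 Cnga3-/- cells and the last 50 of the 61 Pde6ccpfl1 cells. Leading genes were Pdzd9, Nat3 and Lhfp in the wildtype cluster, Usp13, Ildr1 and Twist2 in the Cnga3-/- cluster and Olfr845, Tmem115 and Rbm10 in the Pde6ccpfl1 cluster. None of the 10 leading genes of these 3 clusters was one of the cone or rod markers.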

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

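The scaling to nuclear oxidative phosphorylation and ribosomal protein genes, the use of only the wells kept in all 3 plates and the list sums without 2 members were chosen after the data were seen, and the other alternatives before. No paired analysis was possible because each genotype has 1 library, and no replicate could be left out. Of 1075 values of the 72 named gene results, 4 reversed and 22 were under 2-fold. Without being counted as reversed, 151 values left the interval of the main result. These genes were chosen for 1 direction in the mean CPM over cells and in odd-numbered and even-numbered cells. They could therefore not reverse in those alternatives. A list sum was counted as reversed only where its main interval left out 1, and a list median only where it stood apart. By this count list sums reversed in 11 of 753 planned and 17 of 189 added values. A further 132 planned and 64 added values of list sums left the main interval without being counted as reversed. No list median was counted as reversed in 383 planned and 75 added values. Most of these could not be, since only rod genes in Cnga3-/- against wildtype and ribosomal proteins between the mutants stood apart. Unless a reason is given, the cause was not tested. Depth limits what single cone and rod markers can show, since each had 63 counts or fewer in every library.

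Using only cells with at least 3 detected cone markers leaves 2 wildtype cells and so fewer counts. There, 42 and 52 genes were at least 2-fold lower in Cnga3-/- and in Pde6ccpfl1 than in wildtype, 220 were at least 2-fold higher in Pde6ccpfl1 than in Cnga3-/-, and the Pearson correlation of the mutant comparisons was 0.823. In Cnga3-/- against wildtype the log2 ratio was -0.67 for Gje1, -1.15 for Tlk2 and -0.23 for Twsg1, and in Pde6ccpfl1 against wildtype -0.87 for Slc38a11. The list sums had log2 ratios of -0.058 for ribbon synapse, 0.20 for cell death and 0.94 for proteasome and ubiquitin in Cnga3-/- against wildtype, 0.16 for actin and myosin in Pde6ccpfl1 against wildtype and -0.55 for photoreceptor transcription factors between the mutants.

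Thinning every cell and changing the gene filter alter how many genes are compared. With thinning, 41 genes were higher and 58 lower in Cnga3-/- than in wildtype, 42 and 44 in Pde6ccpfl1 than in wildtype, and 24 and 35 in Pde6ccpfl1 than in Cnga3-/-. The log2 ratio of ribbon synapse in Cnga3-/- against wildtype was -0.018, that of nuclear migration and microtubule motors between the mutants 0.0081, and the Pearson correlation 0.899. With a filter of 10 counts the numbers were 1248 and 1166, 1130 and 1238, and 795 and 1111, with a correlation of 0.777. With 200 counts they were 35 and 35, 35 and 39, and 28 and 21, with a correlation of 0.892.

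In odd-numbered cells 120 genes were higher in Cnga3-/- than in wildtype and 229 in Pde6ccpfl1 than in Cnga3-/-. There the log2 ratio of photoreceptor injury, immune and growth factor was -0.047 in Pde6ccpfl1 against wildtype, that of photoreceptor transcription factors -0.36 between the mutants, and the Pearson correlation 0.738. In even-numbered cells 118 genes were higher in Cnga3-/- than in wildtype. The log2 ratio of actin and myosin was 0.20 in Cnga3-/- and 0.73 in Pde6ccpfl1 over wildtype, and the correlation 0.778.

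Scaled to nuclear oxidative phosphorylation and ribosomal protein genes, 1008 and 914 genes were at least 2-fold lower in Cnga3-/- and in Pde6ccpfl1 than in wildtype, since those sums are higher in both mutants. In Cnga3-/- against wildtype the log2 ratios were -0.70 for ribbon synapse, -0.67 for outer segment and cilium and -0.026 for cytosolic ribosomal proteins. In Pde6ccpfl1 against wildtype they were -0.62 for cone phototransduction, -0.024 for oxidative phosphorylation (nuclear genes), -0.57 for glycolysis and lactate and -0.63 for photoreceptor injury, immune and growth factor. In the wells kept in all 3 plates 78 genes were higher and 88 lower in Cnga3-/- than in wildtype, 80 and 160 in Pde6ccpfl1 than in wildtype, and the Pearson correlation was 0.773. With wildtype cells split between the comparisons it was 0.541, which removes the shared counts but not the shared plate. Resolution 1 gave 7 clusters.

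Leaving out the 2 members of each list with the most counts removes the genes that set some sums. The log2 ratio was then 0.46 for actin and myosin, 0.39 for ER stress and protein folding and 0.25 for proteasome and ubiquitin in Cnga3-/- against wildtype. In Pde6ccpfl1 against wildtype it was 0.68 for actin and myosin and -0.47 for photoreceptor injury, immune and growth factor. Between the mutants it was -0.042 for cone phototransduction, -0.0036 for photoreceptor transcription factors, -0.012 for ER stress and protein folding, -0.044 for photoreceptor injury, immune and growth factor and -0.12 for proteasome and ubiquitin.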

Other observations

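The tests of explanations in this part were chosen after the results they address were seen, while the marker and list sums they draw on were planned. Malat1, a nuclear long noncoding RNA singled out after its values were seen, had 22 counts in wildtype, 295 in Cnga3-/- and 165 in Pde6ccpfl1, which is 10.9-fold and 6.94-fold higher than in wildtype. Il18, a cytokine gene among the 10 most abundant, had 1241 CPM in wildtype, 30060 in Cnga3-/- and 7359 in Pde6ccpfl1. Vomeronasal receptor genes, which detect pheromones, stood at 1.77, 1.06 and 1.08 CPM per kilobase of exon in wildtype, Cnga3-/- and Pde6ccpfl1. Within 15 Mb of Chrnb4, 5 of 35 compared genes were at least 8-fold higher in both mutants and 7 at least 4-fold higher, namely Il18, Peak1, Sin3a, Kif23, Dapk2, Usp3 and Rora, against 60 and 82 of 1464 compared genes in the whole genome. Of 16 compared genes near Cnga3 none was at least 8-fold higher in both and 1 at least 4-fold, Vwa3b (chromosome 1, 37026596 to 37187613), at 5.40-fold in Cnga3-/- and 4.33-fold in Pde6ccpfl1. Of 13 near Pde6c none was at least 4-fold higher in both.

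Depth followed the position of the well in the plate. Between plates, counts of the wells at the same position had Pearson r = 0.722 and Spearman correlation = 0.790 for Cnga3-/- and wildtype (60 wells), 0.749 and 0.750 for Pde6ccpfl1 and wildtype (57 wells), and 0.828 and 0.833 for Pde6ccpfl1 and Cnga3-/- (70 wells). The largest r among 10000 shuffles of the wells was 0.5001, 0.527 and 0.435. Without the 2 farthest wells r was 0.690, 0.761 and 0.817. Across 21750 genes, counts and exonic length had Spearman correlation of 0.571, 0.581 and 0.561 in wildtype, Cnga3-/- and Pde6ccpfl1.

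The most abundant genes were not photoreceptor genes. Another retinal cell type in the sort stays open. Of the other retinal types' marker sets the highest, rod markers in Cnga3-/-, reached 4.15 times the olfactory receptor level per kilobase (upper bound 4.68), and the highest outside rods, horizontal cell markers in wildtype, reached 2.24 times (upper bound 2.70). The markers of the sorted cones themselves reached 1.09 times that level in wildtype, 5.40 in Cnga3-/- and 4.48 in Pde6ccpfl1, so a low marker level does not exclude a cell type here. Partial matches to the SMART-seq2 primer may contribute: pieces of 9 bases of the primer were 1.90 times as frequent in 298 of the most abundant transcripts as in matched low-count transcripts, against a median of 1.16 and an upper bound of 1.48 for shuffled primers. Counts that do not come from expressed transcripts also stay open. Olfactory receptors had 0.742 to 0.887 times the level per kilobase of other protein-coding genes. The 300 most abundant genes were left out of the other protein-coding genes but not of the olfactory receptors. The olfactory receptors thus kept Olfr845, with 0, 54 and 488 counts in wildtype, Cnga3-/- and Pde6ccpfl1, and Olfr410, with 2, 246 and 143. Vomeronasal receptor genes were lower, at 0.392, 0.294 and 0.259 times the olfactory receptor level in wildtype, Cnga3-/- and Pde6ccpfl1. Because the 300 genes were left out of the other protein-coding genes, these values cannot tell why the most abundant genes lead. Apart from cell type, no biological explanation was tested for this pattern, and the primer sequence is from general knowledge, not from the labels.

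Cone marker, rod marker, ribosomal protein and nuclear oxidative phosphorylation sums were lower in the wildtype library. These sums are scaled to the library totals, and the median of counts per kept cell was highest in wildtype (4895), so depth was not weighed further. Less cell-derived RNA relative to background in the wildtype library may account for part of it, as the ribosomal and nuclear oxidative phosphorylation sums were at least 1.78 times higher in the mutants, but mitochondrially encoded genes were at most 0.965 times the wildtype level (upper bound 1.19), so this stays open. Genotype cannot be told apart from plate with 1 library per genotype, nor can an age difference if the tag in the well names is an age.

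A set of 60 genes was at least 8-fold higher in both mutant libraries than in wildtype. Blocks of linked DNA that differ between the lines stay open, for the whole set or for part of it. In the set, 12 pairs of genes lay within 5 Mb of each other, against a mean of 9.28 and a middle 95% of 4 to 16 in random sets. Near the annotated position of Chrnb4 lay 5 of the 60 genes. Cells of all the lines were GFP-positive, and these counts do not show where the reporter lies in any line. Those 5 genes therefore do not tie a block of DNA to the reporter. Genotype and library preparation cannot be told apart for these 60 genes, because each genotype has 1 plate.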
